A study of Drosophila melanogaster with 4 samples.

How the data were processed

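RNA was taken from fat bodies of yw larvae at 110 h after egg laying, 10 fat bodies per sample, with 2 samples of dMef2-Gal4 larvae carrying a white RNAi construct (Con) and 2 carrying an ND-75 RNAi construct (ND-75-i), per the labels' protocols. Libraries were sequenced on an Illumina HiSeq2000, per the labels. The labels do not say that replicates came from separate crosses or days, so p-values measure only the spread between these samples, which may be technical.

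The authors deposited gene FPKM tables, 1 per library, with 14146 entries each, a lower and an upper bound and a status per gene, per the file headers. Bowtie 0.12.2 is named in the submitters' processing notes. The program and version that computed the FPKM, the annotation, the strand setting and the genome build are not given in the sources used here. Coordinates are printed as in the deposited tables with 1 added to each start, and the chromosome names there include unplaced and heterochromatic arms. Of 13990 distinct symbols, 93 stood on more than 1 line and 13747 (98.26%) were matched to a current symbol in the annotation at hand, which was used for names and exon lengths only. Con replicate 1 held 5 gene names turned into dates by a spreadsheet, which were matched by position.

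FPKM are not counts, so count tests were not used, although the design had named them in case the values were counts. The deposited bounds imply an effective number of fragments for each FPKM, the squared ratio of the FPKM to 0.5 of the upper half-width. That number was whole within 0.05 for 80.7% to 81.9% of genes with 1 start site and under 200 fragments. Other genes were not checked. In voom the implied fragments gave log2 changes, ND-75-i against Con, of -0.78 for Lsd-1 and 1.98 for Desat1. Those from FPKM were -0.17 and 1.41. For ND-MNLL the values were close, 1.77 and 1.78. The implied numbers are thus not fragment counts for every gene. They correspond to 9573000, 9799000, 11877000 and 10643000 fragments in Con replicates 1 and 2 and ND-75-i replicates 1 and 2. FPKM of different libraries share the library's total, and the 10 highest genes took 35.5% and 33.1% of summed FPKM in Con and 18.8% and 20.1% in ND-75-i. The 0 listed for genes with a status of too many fragments is a failed estimate.

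Genes with a status of OK in all 4 libraries (13882 symbols; 108 were left out) and an FPKM of at least 1 in at least 2 libraries were tested, 10023 in all. limma 3.58.1 in R 4.3.3 was run on log2(FPKM + 1) with an intensity trend and group as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual and 1.95 prior degrees of freedom. Log2 changes on this scale understate those of genes with low FPKM. The 37 gene lists were tested with camera at a preset correlation of 0.01 and again with a correlation estimated from the residuals, and members were also adjusted over the list alone. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

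The groups, the test, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where said otherwise. Named genes were ND-75 and w; the 8 largest changes in each direction among genes past the threshold with groups that do not overlap and a mean of at least 10 FPKM; up to 3 members past the threshold per functional list, smallest p first; a fixed set of signalling and lipid genes; and the 2 most abundant members of each marker list. Any other gene named was chosen after its values were seen.

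The procedure was tested on simulated data for ND-75-i against Con with 200 of 9840 genes changed, and a further 30 in a planted list. It called 56 of 100 genes changed 2-fold and 97 of 100 changed 4-fold in the right direction, with median log2 changes of 0.94 and 1.85, and 9 of 9610 unchanged genes. With no gene changed it called 1 of 9837. The planted list of 30 genes changed 2-fold had a camera adjusted p of 1.39e-47 and 0 of 20 unchanged lists were called. With an estimated correlation camera missed the planted list (adjusted p = 0.154). Simulated genes varied independently, the 200 changes were split evenly between directions, and libraries had no shift. The error rates of limma and camera on real data with correlated genes and a shift therefore cannot be read from it.

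Alternatives were median-ratio rescaling, quantile normalization, pseudocounts of 0.1 and 5, no low filter, a mean of at least 5 FPKM, the replicate number as a block, each library left out in turn, an estimated correlation and a 2-fold minimum. Keeping genes of low-data or failed status, and voom weights on the fragments implied by the bounds without and with median-ratio factors, were added after the data were seen.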

Results

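Messenger RNA was measured in fat bodies, the larval organ of nutrient storage and metabolism, dissected from Drosophila melanogaster larvae of the last instar at 110 h after egg laying. Each sample pooled 10 fat bodies. In the ND-75-i group, the muscle driver dMef2-Gal4 expressed an RNAi construct against ND-75, a core subunit of mitochondrial complex I. In the Con group, the same driver expressed RNAi against white, the eye pigment transporter gene. Each group had 2 samples, and the comparison asks how the fat body transcriptome differs when complex I is perturbed in muscle. Values were FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library. They summed to 861027 and 849472 in the Con libraries and to 957235 and 942561 in the ND-75-i libraries. The bounds deposited with the FPKM correspond to about 9573000 and 9799000 fragments in Con replicates 1 and 2 and to 11877000 and 10643000 in ND-75-i replicates 1 and 2. Pairs of FPKM below are replicate 1 and replicate 2 of a group, changes are on the log2(FPKM + 1) scale as ND-75-i minus Con, and every named gene rests on 2 libraries per group.

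ND-75, listed as ND75 on chromosome X at 8142684 to 8145699, was higher in the fat bodies of the ND-75-i group, a tissue other than the muscle that the driver targets. It stood at 46.6 and 43.9 FPKM in Con and at 94.8 and 79.0 FPKM in ND-75-i, a log2 change of 0.92 (SE 0.125, adjusted p = 0.0353). After median-ratio rescaling of the libraries the change was 0.63 and missed the threshold (adjusted p = 0.0793), as it did after quantile normalization (0.65, adjusted p = 0.0515). The control target w was at 2.48 and 5.37 FPKM in Con and 2.11 and 6.96 FPKM in ND-75-i (adjusted p = 0.925). Neither value measures the knockdown in muscle.

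Of 10023 genes tested, 778 were higher and 109 were lower in ND-75-i at an adjusted p below 0.05. The rises included many genes of mitochondrial energy production and of the mitochondrial ribosome, and the falls included the storage protein gene Lsp1alpha and the ornithine aminotransferase gene Oat. For 75.4% of the genes tested the values of the groups did not overlap, 5380 with ND-75-i above and 2174 with ND-75-i below, against 33.3% by chance. Across genes, log2 values correlated at 0.960 between Con replicates and 0.961 between ND-75-i replicates, against 0.855 to 0.914 between groups. Genes are not independent replicates. The median gene was 0.25 higher on the log2 scale in ND-75-i, and median-ratio rescaling brought this to -0.01 and gave 348 higher and 139 lower genes. The share of higher genes among the calls went from 87.7% to 71.5%, and quantile normalization gave 605 higher and 379 lower (61.5%). With 1 library left out, limma called 0 genes without Con replicate 1, Con replicate 2 or ND-75-i replicate 1, and 2 higher and 1 lower without ND-75-i replicate 2. All 778 and 109 genes kept their sign there. They were picked with all libraries in, so this was largely fixed in advance and adds no support. These limits hold for the members of every list below.

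Nearly all measured subunits of the respiratory chain were higher in ND-75-i. Of 33 nuclear subunits of complex I, the NADH dehydrogenase, 31 rose and 0 fell over all genes tested, and 32 rose when adjusted over the list alone; the median log2 change was 1.32, or 2.50-fold. ND-MNLL went from 116 and 117 FPKM to 426 and 379 FPKM (log2 change 1.78, SE 0.0951, adjusted p = 0.0182), ND-B15 from 87.6 and 82.3 to 227 and 220 FPKM, and ND-MWFE from 76.1 and 79.4 to 223 and 205 FPKM. Of 35 nuclear subunits of complexes II to V, 34 rose over all genes and 34 adjusted over the list alone, with a median log2 change of 1.44. ATPsyndelta, of the ATP synthase, rose by 1.52 (SE 0.0815), Cyt-c1, of complex III, by 1.70 (SE 0.103), and the succinate dehydrogenase subunit SdhB by 1.56 (SE 0.0971). The 1 member that did not pass, ATPsynepsilonL, named here after its value was seen, lay at 10.9 and 8.61 FPKM in Con and 5.37 and 2.07 FPKM in ND-75-i (adjusted p = 0.119) and was lower when adjusted over the list alone. The summed FPKM of the muscle markers, genes of the tissue in which RNAi was driven, was 172.5 and 164.2 in Con and 232.9 and 201.7 in ND-75-i. Both lists stood above other genes by camera (adjusted p = 3.68e-14 and 1.04e-14). Neither call held with a correlation estimated from the residuals (adjusted p = 0.756 with an estimated correlation for both). After median-ratio rescaling 28 and 33 members were higher. With any 1 library left out limma called 0 in either list, while 32 to 33 and 34 were higher at an unadjusted p below 0.05.

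**Figure D1:**
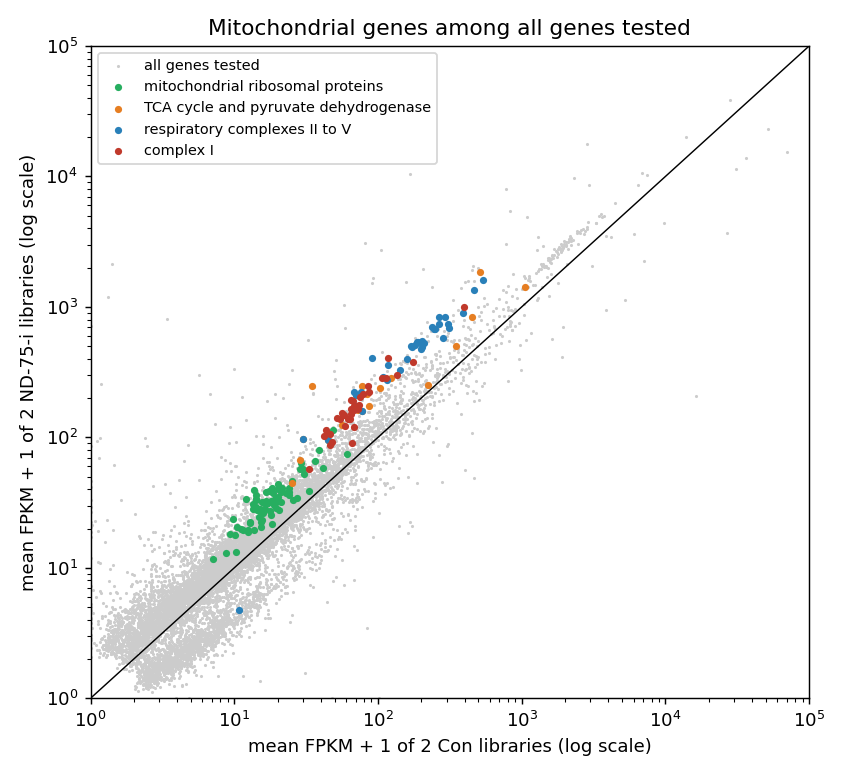
Mean FPKM + 1 of the 2 Con libraries (horizontal, log scale) against that of the 2 ND-75-i libraries (vertical, log scale), 1 point per gene, with the line of equal values. Complex I and complexes II to V lie above the line with median log2 changes of 1.32 and 1.44, apart from ATPsynepsilonL below it.

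Enzymes that feed the chain were higher as well. In the TCA cycle and pyruvate dehydrogenase list, 17 of 20 genes rose and 0 fell, and 19 rose adjusted over the list alone. The median log2 change was 1.18 (camera adjusted p = 8.83e-09; adjusted p = 0.756 with an estimated correlation). The largest rise was that of kdn, the citrate synthase gene, from 32.2 and 34.7 FPKM to 275 and 220 FPKM (log2 change 2.84, SE 0.141, adjusted p = 0.0182). ScsbetaA, of succinyl-CoA synthetase, rose by 1.23, whereas the GTP-specific subunit ScsbetaG, named after its value was seen, was at 216 and 228 FPKM in Con and 253 and 248 FPKM in ND-75-i. Among 72 mitochondrial ribosomal proteins 32 rose, and 63 adjusted over the list alone. Their median log2 change was 0.82 (camera adjusted p = 1.03e-12; adjusted p = 0.756 with an estimated correlation). mRpL28 rose by 1.12, mRpL23 by 1.48 and mRpL1 by 1.18. Rescaling by median ratios gave 13 and 14 higher members in these lists, quantile normalization 13 and 19, voom weights 15 and 19, and voom weights with median-ratio factors 9 and 5. Of 23 heat shock and mitochondrial stress genes, 8 rose over all genes and 14 adjusted over the list alone, with a median of 0.81 (camera adjusted p = 0.0106; adjusted p = 0.756 with an estimated correlation). They included the mitochondrial chaperones Hsp60 (log2 change 1.93, SE 0.158) and Hsc70-5 (1.09, SE 0.0876), and CG11267, the Hsp10 gene (1.32, SE 0.0883). Cytosolic Hsp70 genes, near-identical copies named after their values were seen, also rose, among them Hsp70Bbb, from 0.499 and 0.403 FPKM to 5.996 and 6.57 FPKM. The camera call of this list was lost under a stricter low filter (adjusted p = 0.209), and voom weights called 5 members, or 4 with median-ratio factors.

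The cytoplasmic ribosome moved by less. Of 89 cytoplasmic ribosomal proteins, 13 rose over all genes and 80 adjusted over the list alone. The median log2 change was 0.56 (camera adjusted p = 3.19e-09; adjusted p = 0.756 with an estimated correlation). RpL11 went from 1607 and 1727 FPKM to 2684 and 2833 FPKM (log2 change 0.73). RpL24-like rose by 1.14 and RpL7-like by 0.83. After median-ratio rescaling limma called 0 members, with 24 higher and 1 lower at an unadjusted p below 0.05, and voom weights on the unscaled libraries called 5. Quantile normalization gave 1 higher member, no low filter 3 and a pseudocount of 0.1 gave 8, whereas a pseudocount of 5 gave 32 and the stricter low filter 73. The list was not enriched after quantile normalization, where its median was 0.03 (adjusted p = 0.660). Ribosomal paralogs RpL22-like (8.73 and 6.78 against 5.72 and 1.63 FPKM) and RpS19b (23.1 and 15.4 against 14.495 and 4.11 FPKM), named after their values were seen, lay lower without passing (adjusted p = 0.203 and 0.223). In the ribosome biogenesis list, 1 of 22 genes rose, Non1 (log2 change 0.97), and 11 did adjusted over the list alone, with a median of 0.64 (camera adjusted p = 0.00217; adjusted p = 0.756 with an estimated correlation). Under the stricter low filter 5 of them were higher. Quantile normalization left 0, with Non1 at a limma adjusted p of 0.0646, as did voom weights with median-ratio factors (0.056).

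Carbohydrate genes showed fewer but in part large rises. In glycolysis 3 of 14 genes rose, 5 adjusted over the list alone, with a median log2 change of 0.51 (camera adjusted p = 0.00774; adjusted p = 0.756 with an estimated correlation). The hexokinase gene Hex-C went from 0.216 and 0.371 FPKM to 26.8 and 17.8 FPKM, Gpdh1, of glycerol 3-phosphate synthesis, rose by 1.76 (SE 0.138), and Hex-A rose by 0.82, a call lost after median-ratio rescaling (adjusted p = 0.0806) and quantile normalization (0.0573). In the trehalose, glycogen and gluconeogenesis list 5 of 14 genes rose, and 10 rose and 1 fell adjusted over the list alone, with a median of 0.76 (camera adjusted p = 0.0358; adjusted p = 0.756 with an estimated correlation). Pepck, which commits carbon to gluconeogenesis, went from 335 and 579 FPKM to 2277 and 1837 FPKM (log2 change 2.21, SE 0.313, adjusted p = 0.0378, and 0.0501 after quantile normalization), and fbp, fructose-bisphosphatase, rose by 1.21. The trehalose synthase gene Tps1 was at 232 and 234 FPKM in Con and 419 and 348 FPKM in ND-75-i (adjusted p = 0.0505), and passed with a pseudocount of 5 (0.0475) and the stricter low filter (0.0410). Without Con replicate 2 both lists lost their camera call (adjusted p = 0.0968 and 0.123), the second also without ND-75-i replicate 1 (0.0638), and both lost it after quantile normalization (0.727 and 0.0960). The median of the glycolysis list was 0.32 without ND-75-i replicate 1. With voom weights the second list had an adjusted p of 0.0575, or 0.0505 with median-ratio factors, and it had 2 higher members under either rescaling.

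Lipid genes were mixed. Of 23 lipid synthesis and droplet genes 6 rose and 0 fell, 9 adjusted over the list alone, with a median log2 change of 0.50 (camera adjusted p = 0.157, and 0.0420 without ND-75-i replicate 2; adjusted p = 0.779 with an estimated correlation over all libraries). After median-ratio rescaling 1 was higher, after quantile normalization 2 were higher and 1 lower, and with voom weights or no low filter 3 were higher. ACC, acetyl-CoA carboxylase, listed as CG11198, went from 57.7 and 44.4 FPKM to 319 and 174 FPKM (log2 change 2.20, SE 0.346, adjusted p = 0.0433), and Desat1 rose by 1.41; the ACC call was lost after median-ratio rescaling (1.91, adjusted p = 0.0686) and the Desat1 call after quantile normalization (adjusted p = 0.0601). FASN1, fatty acid synthase, was at 586 and 450 FPKM in Con and 1135 and 684 FPKM in ND-75-i (adjusted p = 0.150), and the perilipin gene Lsd-1 at 1213 and 1330 against 1172 and 1091 FPKM (adjusted p = 0.283, and 0.0449 after quantile normalization, with a log2 change of -0.66). Of 21 lipolysis and fatty acid oxidation genes 4 rose, and 7 rose and 1 fell adjusted over the list alone. After median-ratio rescaling limma called 0, with 6 higher and 1 lower at an unadjusted p below 0.05, and after quantile normalization 0 higher and 1 lower, while voom weights on the unscaled libraries called 4 higher. The median was 0.28 (camera adjusted p = 0.0397; adjusted p = 0.756 with an estimated correlation), which was -0.00 after median-ratio rescaling and -0.06 after quantile normalization. Its camera call was lost under both scalings (0.519 and 0.867), under the stricter low filter (0.152), with voom weights (0.0575, and 0.411 with median-ratio factors) and without Con replicate 2 (0.0968), ND-75-i replicate 1 (0.0659) or ND-75-i replicate 2 (0.0750). The triglyceride lipase gene bmm was at 38.2 and 41.5 FPKM in Con and 46.2 and 44.7 FPKM in ND-75-i (adjusted p = 0.210), a difference of -0.10 after median-ratio rescaling. Of 8 lipoprotein genes 1 rose over all genes, Apoltp (log2 change 1.39), and 1 rose and 1 fell adjusted over the list alone, with a median of 0.07 (camera adjusted p = 0.370), -0.20 after median-ratio rescaling. After that rescaling limma called 0 of the lipoprotein genes higher and 1 lower, and Apoltp missed the threshold (adjusted p = 0.0817). Here, as for the secreted signals, detoxification and ecdysone lists below, the median and mean were above 0 and the camera direction was lower. Camera compares the moderated t statistics of a list, not its log2 changes, with those of all other genes.

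Few genes of the signalling pathways passed. In the TGF-beta and Activin list, limma called 0 of 17 genes, over all genes and adjusted over the list alone, with 7 higher at an unadjusted p below 0.05. Voom weights gave 0 calls as well (median log2 change 0.40, camera adjusted p = 0.109, and adjusted p = 0.779 with an estimated correlation over all libraries). A pseudocount of 5 and the stricter low filter each called 1 higher member. The Activin receptor gene babo was at 13.1 and 11.9 FPKM in Con and 17.4 and 16.1 FPKM in ND-75-i (adjusted p = 0.111, a change of 0.40, 0.12 after median-ratio rescaling). Smox, its transcription factor, was at 21.6 and 26.7 against 33.6 and 32.4 FPKM (0.112, a change of 0.44, 0.16 after median-ratio rescaling). The ligand gene daw was at 54.2 and 70.5 against 63.1 and 66.7 FPKM (0.755; a change of 0.07, -0.22 after median-ratio rescaling), and Actbeta at 0.702 and 0.501 against 2.34 and 1.81 FPKM (0.0848). Of 14 AKH pathway genes 1 rose, also adjusted over the list alone (median 0.29, camera adjusted p = 0.0901, and 0.0128 without Con replicate 1 and 0.0479 with no low filter; adjusted p = 0.756 with an estimated correlation over all libraries). It was AkhR, the receptor of the adipokinetic hormone, listed as GRHR, at 73.9 and 70.3 against 131 and 129 FPKM (log2 change 0.84, SE 0.0796, adjusted p = 0.0220), and after median-ratio rescaling it missed the threshold (0.55, adjusted p = 0.0792). Of 23 insulin, TOR and FOXO genes 1 rose and 1 fell, and limma called 0 adjusted over the list alone, with 8 higher and 2 lower at an unadjusted p below 0.05 and 1 higher with voom weights (median 0.31, camera adjusted p = 0.564). ImpL2, a secreted insulin antagonist, fell by 0.71 (SE 0.102, adjusted p = 0.0387, and 0.179 with voom weights), and srl, a coactivator of mitochondrial genes, rose by 0.87 (adjusted p = 0.0498), a call lost after median-ratio rescaling (0.0822). InR was at 1.68 and 1.76 against 3.39 and 2.74 FPKM (adjusted p = 0.132), and Thor at 662 and 1147 against 1313 and 1411 FPKM (0.186). Of 12 secreted signal genes 3 rose and 1 fell, and 3 rose and 2 fell adjusted over the list alone (median 0.13, -0.16 after median-ratio rescaling, camera adjusted p = 0.657). Nplp2 went from 2861 and 2827 FPKM to 19506 and 15830 FPKM (log2 change 2.63, SE 0.167). The gene sun, which encodes the epsilon subunit of ATP synthase and also a secreted peptide, rose by 1.52. It stood outside the list of complexes II to V. Gbp2 rose by 0.63, a call lost after median-ratio rescaling (limma adjusted p = 0.108).

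**Figure D2:**
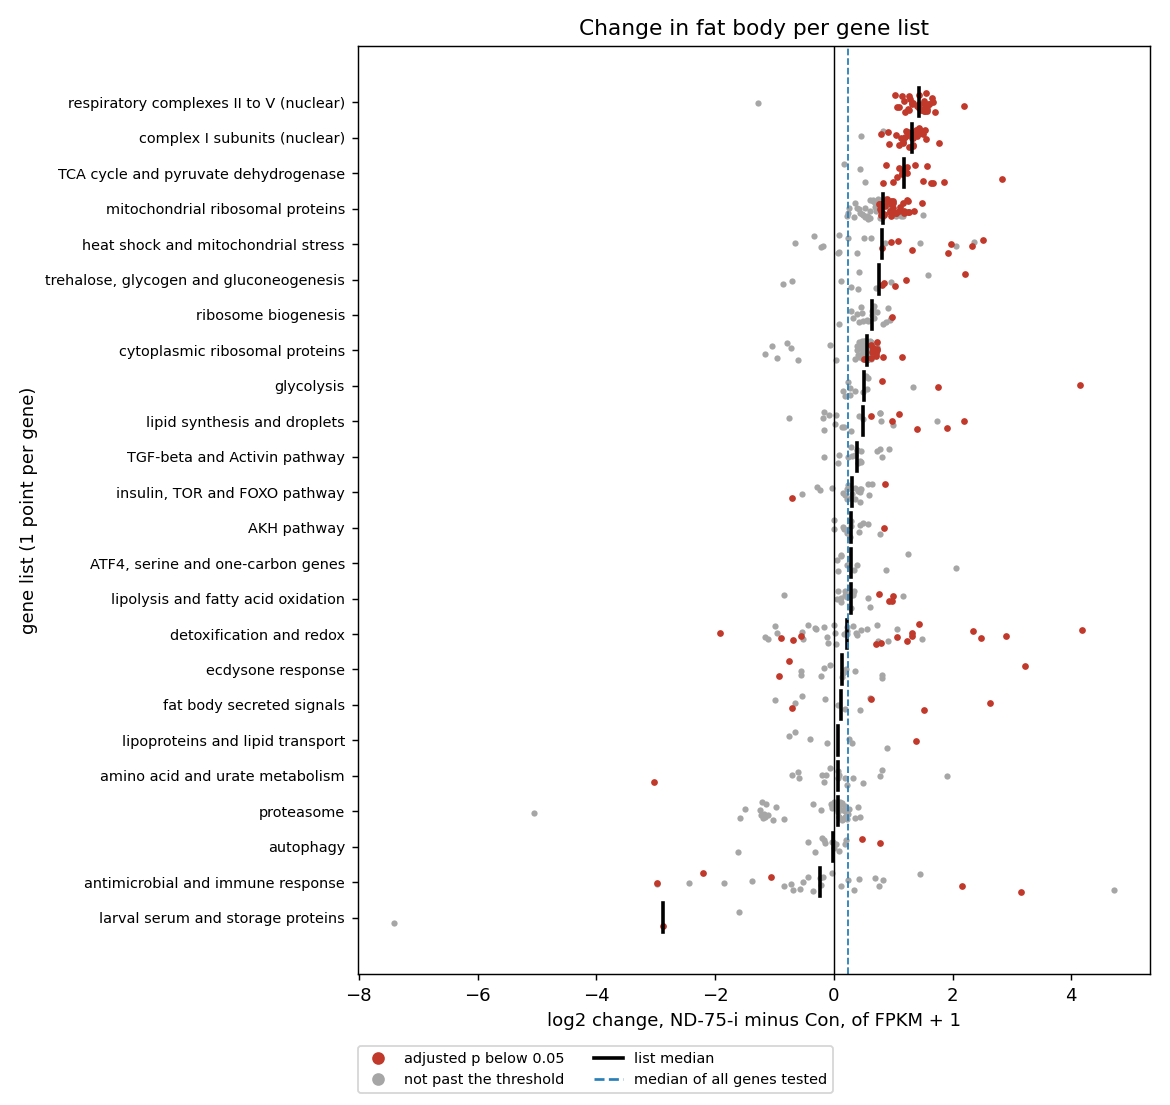
Log2 change of FPKM + 1, ND-75-i minus Con (horizontal), for each gene of the functional lists (vertical, 1 point per gene), with genes past an adjusted p of 0.05 in red, list medians as black bars and the median of all genes tested, 0.25, as a dashed line. Medians run from -2.88 for the larval serum and storage proteins to 1.44 for respiratory complexes II to V.

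Among storage protein genes of the late larval fat body, 1 of the 3 that could be tested fell in ND-75-i. It was Lsp1alpha, a larval serum protein, which went from 28004 and 25267 FPKM to 2893 and 4506 FPKM (log2 change -2.88, SE 0.272, adjusted p = 0.0220). Fbp1, the receptor for storage protein uptake, was at 14971 and 17897 FPKM in Con and at 22.5 and 393 FPKM in ND-75-i, just short of the threshold (adjusted p = 0.0594). It passed under the stricter low filter (0.0472) and without ND-75-i replicate 2 (0.0494). Fbp2 was at 29136 and 33073 against 6380 and 16337 FPKM (adjusted p = 0.116). Adjusted over the list alone, 3 fell (camera adjusted p = 0.00240; adjusted p = 0.756 with an estimated correlation). Lsp1beta and Lsp1gamma were listed at 0 in all 4 libraries and Lsp2 in both Con libraries with a status of too many fragments, so these zeros are not levels; Lsp2 was at 16637 and 25411 FPKM in ND-75-i. Among 15 ecdysone response genes 1 rose and 2 fell, and 1 rose and 3 fell adjusted over the list alone (median 0.15, camera adjusted p = 0.314, and 0.0489, lower, under the stricter low filter; adjusted p = 0.756 with an estimated correlation over all genes tested), with a median of -0.13 after median-ratio rescaling. Cyp18a1, which inactivates ecdysteroids, went from 0.174 and 0.145 FPKM to 10.0 and 9.72 FPKM, while shd, which converts ecdysone to its active form, fell by 0.76 and Cth, listed as Eip55E, by 0.92. With voom weights Cyp18a1 missed the threshold (adjusted p = 0.104).

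**Figure D3:**
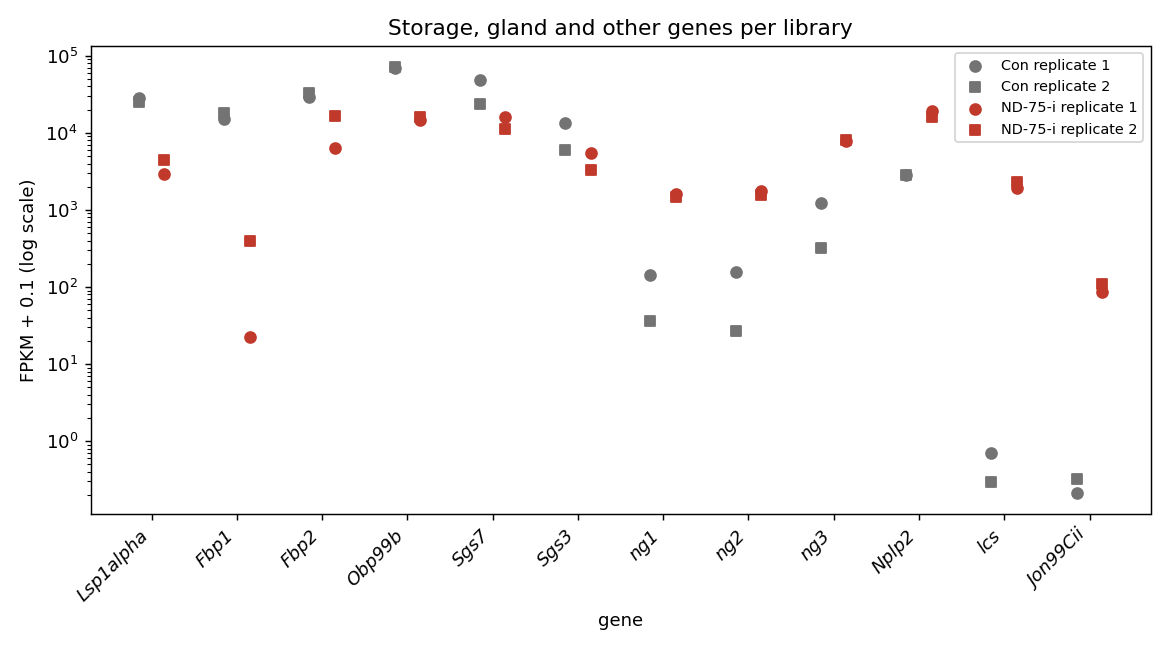
FPKM + 0.1 (vertical, log scale) of storage, salivary gland and other genes (horizontal) in each of the 4 libraries, grey for Con and red for ND-75-i, with circles for replicate 1 and squares for replicate 2. Lsp1alpha lies at 28004 and 25267 FPKM in Con and 2893 and 4506 FPKM in ND-75-i, while lcs lies at 0.610 and 0.199 FPKM in Con and 1910 and 2339 FPKM in ND-75-i.

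Immune and detoxification genes moved both ways. Of 29 antimicrobial and immune genes 2 rose and 3 fell, and 4 rose and 7 fell adjusted over the list alone (median log2 change -0.24, camera adjusted p = 0.0348; adjusted p = 0.756 with an estimated correlation). The attacin gene AttA went from 9.52 and 11.6 FPKM to 0.704 and 0.258 FPKM, and the peptidoglycan recognition genes PGRP-SA and PGRP-SD fell by 1.07 and 2.20 on the log2 scale. Among the Bomanin genes, named after their values were seen, BomS3 rose from 7.08 and 2.32 FPKM to 54.4 and 37.7 FPKM and BomS1 was listed at 0 in Con and at 4.85 and 2.43 FPKM in ND-75-i (adjusted p = 0.0442 and 0.0448). After median-ratio rescaling 0 were higher and 4 lower, with 5 higher and 10 lower at an unadjusted p below 0.05 in limma. After quantile normalization 2 were higher and 8 lower. The camera call of this list was lost after median-ratio rescaling (adjusted p = 0.115) and quantile normalization (0.0960), with no low filter (0.0555), with voom weights (0.0846, and 0.154 with median-ratio factors) and without Con replicate 2 (0.207), ND-75-i replicate 1 (0.0687) or ND-75-i replicate 2 (0.161). The median was 0.25 without Con replicate 2 and 0.11 without ND-75-i replicate 2. Of 44 detoxification and redox genes 11 rose and 4 fell, and 16 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.959); the median of 0.23 was -0.05 after median-ratio rescaling, where 6 were higher and 4 lower, and voom weights gave 5 higher and 2 lower. The cytochrome P450 gene Cyp6w1 went from 9.79 and 10.7 FPKM to 177 and 230 FPKM (log2 change 4.17, SE 0.162, adjusted p = 0.0150), Cyp6a8 rose by 2.35, and Sod2, the mitochondrial superoxide dismutase, by 1.31. In the ATF4, serine and one-carbon list limma called 0 of 10 genes, and 3 adjusted over the list alone, with 3 higher at an unadjusted p below 0.05 and 0 called with voom weights (median 0.28, 0.00 after median-ratio rescaling and -0.04 after quantile normalization, camera adjusted p = 0.245). The replicate block called 3 of them higher, and a pseudocount of 5 and the stricter low filter 1 each. Of 47 proteasome genes limma called 0, over all genes and over the list alone, with 5 higher and 4 lower at an unadjusted p below 0.05 and 0 with voom weights (median 0.06, mean -0.35, camera adjusted p = 0.136). After median-ratio rescaling the proteasome median was -0.22 and camera placed the list below other genes (adjusted p = 2.13e-05; adjusted p = 0.756 with an estimated correlation on the unscaled values). There limma called 0 members, with 0 higher and 12 lower at an unadjusted p below 0.05, and after quantile normalization 2 were lower. Camera also called the list lower after quantile normalization (1.43e-07) and with voom weights and median-ratio factors (0.000837). Of 15 autophagy genes 2 rose, also adjusted over the list alone, Atg13 and ref(2)P (median -0.01, camera adjusted p = 0.190, and 0.0426 after median-ratio rescaling; adjusted p = 0.756 with an estimated correlation on the unscaled values), and neither gene passed after median-ratio rescaling. Of 18 amino acid and urate genes 1 fell, and 2 rose and 3 fell adjusted over the list alone (median 0.07, mean -0.03, median -0.22 after median-ratio rescaling; camera adjusted p = 0.133, lower, and 0.0453 without Con replicate 2; adjusted p = 0.756 with an estimated correlation over all libraries). After quantile normalization 6 were lower, and 3 under the stricter low filter. Camera called the list there as well (0.0273 and 0.0462), and with voom weights and median-ratio factors (0.0468). The gene called in the main comparison was Oat, at 156.3 and 185 FPKM in Con and 19.5 and 20.2 FPKM in ND-75-i (log2 change -3.03, SE 0.117, adjusted p = 0.0150).

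The 8 largest rises and 8 largest falls under the rule for named genes were led by genes close to 0 FPKM in 1 group. lcs, on chromosome X at 21267754 to 21268326, went from 0.610 and 0.199 FPKM to 1910 and 2339 FPKM, and CG33267, on 3L at 11557583 to 11565698, from 0.438 and 0.215 FPKM to 1043 and 1345 FPKM (adjusted p = 0.00441 for both). CG13135 was listed at 0 in both Con libraries and at 1158 and 260.5 FPKM in ND-75-i. CG13947 went from 4.22 and 0.591 to 1030 and 581 FPKM, and CG15741 from 0.373 and 0 to 208 and 302 FPKM. The protease genes Jon99Cii and Jon99Ciii, neighbours on 3R that are similar in sequence, so that the division of reads between them is uncertain, went from 0.114 and 0.223 FPKM to 86.1 and 110.4 FPKM and from 0.108 and 0.106 FPKM to 82.3 and 104 FPKM. The falls were those of CG15772 (24.0 and 36.6 to 0.345 and 0.761 FPKM), Sgs5bis, a relative of the glue gene Sgs5, listed as CG7587 (536 and 391 to 44.1 and 51.2 FPKM), Oat, Lsp1alpha, CG11089 (294 and 505 to 50.8 and 60.3 FPKM) and the maltase gene Mal-A6, listed as CG30360 (46.8 and 53.6 to 5.80 and 9.23 FPKM). Small nucleolar RNAs took places on both sides: snoRNA:Psi18S-1377b was listed at 0 in Con and at 97.3 and 71.4 FPKM in ND-75-i, whereas snoRNA:Me18S-A1576 (67.4 and 132 FPKM) and snoRNA:Psi18S-1854b (38.1 and 56.0 FPKM) were listed at 0 in ND-75-i. With voom weights on the fragments implied by the bounds, CG13135, CG13947, CG15772 and these 3 small nucleolar RNAs missed the threshold.

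Markers of other tissues were measured in the same libraries. Of 18 muscle genes limma called 0, over all genes and over the list alone, with 5 higher at an unadjusted p below 0.05 and 0 with voom weights (median log2 change 0.48, camera adjusted p = 0.815). Tm1, the most abundant, was at 94.2 and 86.6 against 112 and 112 FPKM. Of 9 salivary gland genes 1 rose, ng1, and 3 rose and 3 fell adjusted over the list alone (median -1.09, mean 0.50, camera adjusted p = 0.133, lower, and 0.0453 without Con replicate 2; adjusted p = 0.779 with an estimated correlation over all libraries). The stricter low filter gave 3 higher, and quantile normalization 1 higher and 2 lower. After median-ratio rescaling limma called 0, with 3 higher and 4 lower at an unadjusted p below 0.05, while voom weights on the unscaled libraries called 2 higher. The median was -0.51 without Con replicate 1 and -1.85 without Con replicate 2. The 6 glue genes of the list summed to 81221 and 38549 FPKM in Con and 26342 and 17946 FPKM in ND-75-i. Of 16 midgut genes 5 rose, all of the Jonah protease family, also adjusted over the list alone (median 1.002, camera adjusted p = 0.144, and 0.0132 after median-ratio rescaling, 0.0273 after quantile normalization, 0.0468 with voom weights and median-ratio factors, 0.0137 without Con replicate 2 and 0.0304 without ND-75-i replicate 1; adjusted p = 0.779 with an estimated correlation on the unscaled values; 2 higher with voom weights), while Jon65Aiv, the most abundant, was at 239 and 1819 against 424 and 1317 FPKM. Without Con replicate 1 the midgut median was -0.21, and without Con replicate 2 it was 2.68. The testis list had a median of -1.61 (camera adjusted p = 4.96e-06; adjusted p = 0.756 with an estimated correlation), with limma calling 0 of 13 genes, also adjusted over the list alone, and 3 lower at an unadjusted p below 0.05. Its median was -0.60 without ND-75-i replicate 2. Mst84Da was at 94.8 and 74.1 against 65.3 and 10.6 FPKM, a log2 change of -1.61 (adjusted p = 0.242) that was -0.36 without ND-75-i replicate 2 and -2.87 without ND-75-i replicate 1. The hemocyte list had a median of -0.86 (camera adjusted p = 0.00240, and 0.0680 without ND-75-i replicate 1; adjusted p = 0.756 with an estimated correlation), with 0 of 11 genes called by limma, also adjusted over the list alone, and 1 higher and 2 lower unadjusted. The hemocyte median was -0.19 without Con replicate 2 and -1.36 without Con replicate 1. PPO2 was at 28.9 and 76.4 against 12.6 and 19.9 FPKM (adjusted p = 0.135). The epidermis list had a median of -1.56 (camera adjusted p = 0.0348, and 0.133 after median-ratio rescaling; adjusted p = 0.756 with an estimated correlation), with 0 of 5 genes called by limma, also adjusted over the list alone, and 1 lower unadjusted. It lost its call after quantile normalization (0.180), with no low filter (0.0522), with voom weights (0.0575, and 0.134 with median-ratio factors) and without Con replicate 2 (0.0861; median -0.81) or ND-75-i replicate 1 (0.248). Of 8 neuron genes 1 rose, elav, and 7 adjusted over the list alone (median 1.11, camera adjusted p = 0.0695, and 0.0220 after median-ratio rescaling, 0.0182 after quantile normalization, 0.0221 with no low filter, 0.0346 with voom weights, 0.00678 with voom weights and median-ratio factors and 0.0218 without ND-75-i replicate 2; adjusted p = 0.756 with an estimated correlation on the unscaled values). After quantile normalization 3 were higher, but 0 after median-ratio rescaling or with voom weights and median-ratio factors. The other marker lists did not pass by camera. Of 7 fat body genes 1 rose, Col4a1, and 2 rose and 1 fell adjusted over the list alone (median 0.40, mean -0.57, camera adjusted p = 0.815). In that list 0 were higher after either rescaling, with no low filter or with voom weights and median-ratio factors. The stricter low filter and the replicate block each gave 2. Of 7 Malpighian tubule genes 2 rose, and 3 rose and 1 fell adjusted over the list alone (median 0.31, adjusted p = 0.915; -0.03 without Con replicate 2, 0.74 without Con replicate 1, 0.75 without ND-75-i replicate 1 and 0.16 without ND-75-i replicate 2), with 0 called by limma after median-ratio rescaling (3 higher and 1 lower at an unadjusted p below 0.05; 1 higher with voom weights on the unscaled libraries). For the 4 germline genes (median -0.36, adjusted p = 0.113, and 0.0397 without ND-75-i replicate 1; adjusted p = 0.756 with an estimated correlation over all libraries), 10 imaginal disc genes (0.51, 0.370, and 0.0274 without Con replicate 2; adjusted p = 0.870 with an estimated correlation over all libraries) and 3 oenocyte genes (0.29, 0.912), limma called 0, also adjusted over the list alone, with 0, 2 and 1 higher at an unadjusted p below 0.05. Without 1 library each, their medians ran from -0.64 to -0.07 (without ND-75-i replicate 1 and 2), from 0.04 to 1.02 (without Con replicate 1 and 2) and from -0.74 to 1.32 (without ND-75-i replicate 2 and 1). Of 6 sex-biased genes limma called 0, with 1 higher and 2 lower unadjusted and adjusted over the list alone (median 0.55, mean -0.11, camera adjusted p = 0.518, lower; median -0.23 without ND-75-i replicate 1 and 0.26 without Con replicate 2). With voom weights limma also called 0 in the testis, hemocyte, epidermis, germline, disc, oenocyte and sex-biased lists.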

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

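The tests on salivary gland and Jonah genes, and on scaling and muscle tissue for the respiratory chain, were chosen after the results were seen; the test of gene length was chosen before its result.

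Genes whose deposited status was not OK in every library stood outside the comparison. With such genes kept, 2 of them were higher and 2 lower in ND-75-i past the threshold. CG30503, of low-data status in all 4 libraries, was at 175 and 203 FPKM in Con and 344 and 341 FPKM in ND-75-i, a log2 change of 0.86 (adjusted p = 0.0313 in limma). CG5946, whose estimate failed in ND-75-i replicate 2, was at 42.1 and 44.8 FPKM in Con and 156.001 and 108 FPKM in ND-75-i, a log2 change of 1.56 (adjusted p = 0.0340). CG11474, whose estimate failed in ND-75-i replicate 2, was at 101 and 105 FPKM in Con and 48.3 and 45.7 FPKM in ND-75-i, a log2 change of -1.12 (adjusted p = 0.0186). CG32736, the sloth1 gene, of low-data status in all 4 libraries, was at 7.08 and 4.83 FPKM in Con and 0.004 and 0.001 FPKM in ND-75-i, a log2 change of -2.78 (adjusted p = 0.0220).

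Respiratory chain genes were higher in ND-75-i, with a median log2 change of 1.34 over 68 genes. Scaling by a few very abundant genes does not account for it, since the median was 1.05 after median-ratio rescaling and 61 of the 65 called genes passed there too. A gene length bias would need matched lists to come close, and of 10000 random lists matched on exon length and mean FPKM the upper tail of the medians began at 0.40 and the highest was 0.62. Carried-over muscle would bring its abundant transcripts, and the muscle markers gained 0.317% of the summed FPKM that the respiratory chain genes gained. A difference in developmental point or genetic background between the groups, and an effect of the RNAi in muscle, stay open and were not tested, and which of them may apply is not decided here.

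In the salivary gland list the 3 ng genes had a median log2 change of 4.39 and the 6 glue genes of the list one of -1.40, a gap of 5.79. limma called ng1 and 0 of these 6 (adjusted p of 0.0672 to 0.634), with 3 ng genes higher and 4 of the 6 lower at an unadjusted p below 0.05, and voom weights called 0 of the 6, while Sgs5bis, a relative of Sgs5 outside the list, fell (log2 change -3.24, adjusted p = 0.0182, and 0.0201 with voom weights). In the whole salivary gland list, quantile normalization called 1 higher and 2 lower, and the replicate block 3 higher and 2 lower. The ng and glue sets were told apart by these same values, so the gap decides nothing on less gland tissue in the ND-75-i dissections. That stays open for the glue genes. ND-75-i larvae at an earlier point of the last instar is a candidate explanation, and the ecdysone response list did not decide it (adjusted p = 0.314). With 1 age and 1 genotype per group, stage and genotype cannot be told apart for these genes.

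Of 15 Jonah protease genes 10 rose, those 10 with a median log2 change of 4.12, from summed FPKM of 0.79 and 0.77 in Con to 295 and 406 in ND-75-i. Of the 15, limma called 9 higher after median-ratio rescaling and 7 with voom weights. More midgut tissue of like composition would keep the called genes in a like ratio to the 7 midgut markers of other families. The lowest ratio in ND-75-i (32.7%) was 81.1 times the highest in Con (0.403%). Reads shared with the abundant Jonah genes would keep a like share. The lowest share in ND-75-i (17.6% of the other Jonah genes) was 88.1 times the highest in Con (0.1998%). The 10 genes were picked by their rise in these same values, so higher ratios were partly built in. These ratios alone decide neither explanation, but the levels can be compared. The 7 markers, not picked by call, summed to 196.1 and 1395.6 FPKM in Con and 634.3 and 1243.0 FPKM in ND-75-i. The other Jonah genes, left over by the same calls, summed to 395.9 and 2818.5 FPKM in Con and 722.4 and 2308.4 FPKM in ND-75-i. Con replicate 2 thus held the most of both, with the called genes at 0.77 FPKM. For these 10 genes the levels argue against more midgut tissue of like composition and against reads shared with the other Jonah genes. Midgut tissue of another region or stage, and a difference in genetic background, stay open and were not tested.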

How the results depend on the processing

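The alternatives with voom weights and with low-data genes kept, and the tests reported with them, were chosen after the results were seen. The main limits were 2 libraries per group, a shift of all genes that depends on the scaling, and gene lists that camera calls with a preset correlation only: 15 of 37 lists passed, and 0 with an estimated correlation. That estimate rests on 2 residual degrees of freedom and also missed the list planted in the simulation. Its 0 therefore does not argue against the lists. The estimates ran from -0.326 for oenocyte markers to 0.981 for testis markers, against the preset 0.01. They were 0.775 for complex I and 0.796 for complexes II to V. For lists with genes that correlated, camera p-values at the preset correlation would be too small. The alternatives meant for counts (median-ratio factors in a count model, a second count tool and voom on counts per library) were not run, because FPKM are not counts. Genes higher numbered 348 after median-ratio rescaling, 507 with voom weights, 246 with voom weights and median-ratio factors, and 513 with a 2-fold minimum, against 778. Genes lower numbered 379 after quantile normalization and 67 with a 2-fold minimum, against 109. With voom weights and median-ratio factors 9 TCA cycle genes were higher, against 17. With the replicate number as a block (replicate block), 792 genes were higher and 198 lower; across genes, replicate differences of the groups correlated at 0.357, and the labels do not say that a number marks a shared day. The block gave midgut markers (camera adjusted p = 0.00781), neuron markers (0.0415) and the proteasome (0.0415, lower) a call, and ended that of the antimicrobial (0.0997) and lipolysis (0.0607) lists; summed midgut markers were at 589.5 and 4182.3 FPKM in Con and 1486.3 and 3783.5 FPKM in ND-75-i. With each library left out in turn, 0 to 2 genes were higher and 0 to 1 lower, and 0 members of the complex I, complexes II to V and TCA cycle lists were called by limma; the lone library is then assumed to vary like the other group. The fewer samples may account for the lost calls there, but this was not told apart from dependence on a given library. For the other changes the cause was not tested. The other counts over all genes tested, and of lists enriched at the preset correlation, stayed within 1.5 times. Counts of higher members moved by more than that in 15 of the 37 lists after median-ratio rescaling, 10 after quantile normalization, 13 with voom weights, 21 with voom weights and median-ratio factors, 12 under the stricter low filter, 9 with no low filter, 9 with the replicate block and 6 with either pseudocount, with the widest range for cytoplasmic ribosomal proteins (0 to 73, against 13). Counts of lower members moved by more than 1.5 times in 12 lists after quantile normalization and 8 with the replicate block. They did so in 5 under the stricter low filter, 5 with voom weights and median-ratio factors and 3 with voom weights. Median-ratio rescaling, no low filter and a pseudocount of 5 moved 1 each. Of 103 named genes, 66 were called in the main comparison. Among these 66, 18 lost their call after median-ratio rescaling, 16 after quantile normalization, 15 with voom weights and 31 with voom weights and median-ratio factors. The replicate block lost 5, no low filter 5, a pseudocount of 0.1 lost 2 and keeping low-data genes 1. All of these kept their direction. Calls were gained by Lsd-1 (0.0449), Uro (0.0496) and Yp3 (0.0441) after quantile normalization, Fbp1 (0.0252), Tps1 (0.0489), PPO2 (0.0339) and Lcp3 (0.0179) with the replicate block, Tps1 (0.0410), Fbp1 (0.0472), cpx (0.0431), ap (0.0449) and Uro (0.0487) under the stricter low filter, Tps1 (0.0475) with a pseudocount of 5 and Fbp1 (0.0494) without ND-75-i replicate 2, as adjusted p.

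Log2 changes of the opposite sign after median-ratio rescaling were those of w (-0.14), daw (-0.22), bmm (-0.10), Zasp52 (-0.13), Jon65Aiv (-0.11), Jon65Aiii (-0.16), Irk3 (-0.25) and Cyp4g1 (-0.04). After median-ratio rescaling, the camera direction turned for insulin, TOR and FOXO pathway (0.969) and detoxification and redox (0.767). Log2 changes of the opposite sign after quantile normalization were those of w (-0.10), daw (-0.18), bmm (-0.06), Tm1 (-0.05), Zasp52 (-0.10), Jon65Aiv (-0.30), Jon65Aiii (-0.29), Irk3 (-0.22) and Cyp4g1 (-0.10). After quantile normalization, the camera direction turned for lipolysis and fatty acid oxidation (0.867) and fat body markers (0.867). With a pseudocount of 5, the camera direction turned for detoxification and redox (0.982). With no low filter, the camera direction turned for detoxification and redox (0.866). Under the stricter low filter, the camera direction turned for insulin, TOR and FOXO pathway (0.98), fat body markers (0.99) and Malpighian tubule markers (0.873). With the replicate block, the camera direction turned for detoxification and redox (0.821). Log2 changes of the opposite sign with voom weights were those of w (-0.05), daw (-0.06), Irk3 (-0.13), Cyp4g1 (-0.05) and FASN3 (-0.01). With voom weights, the camera direction turned for detoxification and redox (0.944). Log2 changes of the opposite sign with voom weights and median-ratio factors were those of w (-0.35), daw (-0.30), bmm (-0.14), Adh (-0.16), Tm1 (-0.06), Zasp52 (-0.12), Jon65Aiv (-0.12), Jon65Aiii (-0.17), Irk3 (-0.37), Cyp4g1 (-0.30) and FASN3 (-0.27). With voom weights and median-ratio factors, the camera direction turned for insulin, TOR and FOXO pathway (0.735), fat body secreted signals (0.967), detoxification and redox (0.784) and sex-biased dosage and yolk genes (0.875). With each library left out in turn, log2 changes that turned sign at least once were those of w (-0.60 to 0.76), daw (-0.12 to 0.25), Jon65Aiv (-1.28 to 1.64), Jon65Aiii (-1.14 to 1.40), Zasp52 (-0.21 to 0.50), Irk3 (-0.10 to 0.16), Cyp4g1 (-1.37 to 1.76), lncRNA:roX1 (-0.23 to 2.15), vas (-0.51 to 0.03) and FASN3 (-0.74 to 1.32). List medians that turned sign outside the marker lists were those of lipoproteins (-0.09 to 0.11), secreted signals (-0.00 to 0.28), the antimicrobial list (-0.45 to 0.25), ecdysone response (-0.10 to 0.18), autophagy (-0.09 to 0.04) and amino acid and urate metabolism (-0.03 to 0.08). Camera directions turned at least once for midgut markers (0.0137 to 0.692), imaginal disc markers (0.0274 to 0.827), Malpighian tubule markers (0.541 to 0.906), oenocyte markers (0.0928 to 0.941), fat body secreted signals (0.434 to 0.993) and detoxification and redox (0.692 to 0.906), as the range of adjusted p.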

Other observations

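The limits of 0.5 and 5 FPKM and the families below were chosen after the data were seen. A set of 29 genes lay under 0.5 FPKM in both Con libraries and at 5 FPKM or more in both ND-75-i libraries. All 29 passed in limma, a result largely fixed in advance by limits set on the same values. They held 9 Jonah protease genes and 5 small nucleolar RNAs, with the hexokinase gene Hex-C, the ecdysteroid-inactivating enzyme gene Cyp18a1, the matrix gene prc (0.443 and 0.408 against 22.4 and 14.4 FPKM) and the neighbours CG12506 (listed at 0 in Con, 43.4 and 20.3 FPKM in ND-75-i) and CG13946 (listed at 0, 36.6 and 14.9 FPKM). Only 2 genes lay the other way, both small nucleolar RNAs. Voom results are given here only for members of the set picked by the rule for named genes. Of these, Cyp18a1 (adjusted p = 0.104), CG13135 (0.184) and snoRNA:Psi18S-1377b (0.106) missed the threshold with voom weights. Hex-C, CG33267, CG15741, Jon99Cii and Jon99Ciii passed there. Other members of the set also missed it. The main fit called 5 midgut markers, all Jonah genes of this set, and voom weights called 2 midgut markers. Among 64 families formed from gene symbols with at least 8 members tested, camera also placed the nucleoporin (Nup, 21 genes, median log2 change 0.51, adjusted p = 0.0119) and RNA polymerase (Polr, 29 genes, 0.48, 0.0181) genes above other genes, with adjusted p = 0.923 with an estimated correlation for both. limma called 1 gene of each family, and 0 after median-ratio rescaling, where the medians were 0.25 and 0.20; 14 and 15 were higher at an unadjusted p below 0.05 on the unscaled values, and voom weights called 1 and 0. The UDP-glycosyltransferase genes (Ugt) had 7 higher and 1 lower of 17, and the neprilysin-like genes (Nepl) 8 higher of 17, without passing by camera (adjusted p = 0.153 and 0.485). After median-ratio rescaling these were 6 higher and 1 lower, and 2 higher and 1 lower.

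In the Mst and TTLL families camera placed the members below other genes, while limma called 0 of them. The Mst family had a median log2 change of -1.56 over 15 genes (camera adjusted p = 7.78e-05; adjusted p = 0.923 with an estimated correlation) and the TTLL family one of -0.86 over 9 (0.0250; 0.923), with 1 and 4 members lower at an unadjusted p below 0.05, and 0 and 1 called with voom weights. Without ND-75-i replicate 2 the medians were -0.47 and -0.39, and without ND-75-i replicate 1 they were -2.56 and -1.32. All 13 testis markers tested lay lower in both ND-75-i libraries than in both Con libraries, against 16.7% by chance and 21.7% of all genes tested; the members moved together (estimated correlation 0.981), so they are far from independent. The summed FPKM of the 15 testis markers in the files was 352.6 and 278.7 in Con, 203.3 in ND-75-i replicate 1 and 37.9 in ND-75-i replicate 2. Proteasome paralogs such as Rpt6R (8.60 and 6.62 against 5.40 and 1.05 FPKM) and Rpn12R (9.84 and 4.92 against 3.29 and 0.883 FPKM), both named after their values were seen, had the same order of libraries. So did RpL22-like, RpS19b and ATPsynepsilonL, given above.

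The proteasome gene Prosalpha1 was at 59.4 and 107 FPKM in Con and 4.87 and 0.006 FPKM in ND-75-i (adjusted p = 0.0570), while its neighbouring copy Prosalpha1R, listed as CG30382, was at 90.5 and 109 against 86.6 and 84.2 FPKM, and the division of reads between such similar copies is uncertain. The odorant-binding protein gene Obp99b, named after its values were seen, was at 68905 and 71085 FPKM in Con and 14578 and 16165 FPKM in ND-75-i (log2 change -2.19, SE 0.219, adjusted p = 0.0217). The dosage compensation RNA roX1 was at 27.1 and 16.3 FPKM in Con and 97.0 and 17.8 FPKM in ND-75-i.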
